A study of Mus musculus with 12 samples.

How the data were processed

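Poly-A RNA was sequenced from KP1 mouse cells with an empty vector (EV) or NRF2 overexpression, treated for 16 h with DMSO or 5 nM romidepsin, in 4 groups of 3 libraries. Per the labels, RNA was taken with Trizol and libraries were made with a TruSeq kit. The authors' notes name bcl2fastq 2.19, kallisto 0.44.0, DESeq2 without a version, and the genome build GRCm38. The first deposited table held kallisto estimated counts per gene symbol, which the authors had rounded to whole numbers (100% of values). The second deposited table held a signal that the authors made by dividing each estimated count by 1 factor per library, which matched the DESeq2 median-of-ratios size factor within 1.1e-15. Both tables listed 35013 genes, of which 12331 had no count in any library. Gene positions and identifiers came from GENCODE mouse release M21, joined by symbol (34177 symbols matched once). Estimated counts of near-identical genes depend on how kallisto divided reads that fit more than 1 gene.

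Library totals ranged from 16842824 to 28003010 estimated counts. Single values carry the 95% counting interval of a ratio where a group held 1 to 3 counts, and a floor of 3 counts over the group where it held none. Levels are in CPM, counts scaled to a common library size with TMM factors.

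Genes were kept by the default filter of edgeR on the 4 groups, which left 13502. They were tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit, TMM factors, two-sided) in 1 fit of all 12 libraries with a mean per group and 8 residual degrees of freedom. There were 7 contrasts: 4 pairwise comparisons, the interaction, and the average NRF2 and romidepsin effects. Adjusted p-values are Benjamini-Hochberg values over all genes tested, called under 0.05. The filter keeps a gene silent with DMSO only if romidepsin libraries express it, so rises among such genes are partly fixed by the filter. Log2 fold changes used a prior count of 0.125, and their standard error (SE) is the absolute log2 fold change divided by the square root of F. Levels are given as mean ± SD over 3 libraries.

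Before the data were examined, 30 gene lists with 479 entries were fixed from general knowledge, along with the comparisons, the alternatives and the rule for named genes. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 30 lists within each contrast, with an estimated correlation and fry as alternatives. The histone list held older and newer symbols of the same genes, so that fewer could be tested. Some lists share members, so their results are not independent. H1f0, Cdkn1a, Tubb3 and Cldn3 of the list of genes induced by HDAC inhibitors also stand in other lists. List counts are over all genes tested; the count adjusted over the list alone is printed where it differs. The named genes were Nfe2l2, Keap1 and Trp53, and the 6 largest and 6 smallest log2 fold changes of each comparison among called genes with a mean of at least 5 CPM. For pairwise comparisons these also needed groups without overlapping libraries, which chance gives in 10% of genes for 3 against 3, and predicted genes and pseudogenes were left out. From each list described, up to 4 called members with the largest change and at least 1 CPM could be named, or the 2 most abundant if none was called, and the largest member against the majority. Some genes that this rule names, and the list that served to check the labels, are not reported here.

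The pipeline was tested on simulated data with 200 changed genes in each comparison. Genes changed 2-fold were recovered in 78 to 94% of cases and those changed 1.25-fold in 22 to 58%, and 4.29 to 7.69% of calls were false. A simulated list that shifted was called, and 0 of 30 unshifted lists were. Genes were simulated independently, so this cannot show how often lists of genes that move together are called falsely. Romidepsin called 76.5% of genes in EV and 79.8% in NRF2 cells, far more than were simulated to change. The simulated share of false calls may thus not carry over.

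The alternatives were RLE, upper-quartile and library-size scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on the deposited normalized values with a pseudocount of 1, fits of the groups compared alone, the replicate number as a block, stricter thresholds, and leaving out each library. Counts of list members without replicate 3 of NRF2 cells with DMSO were singled out after that library was seen to stand apart. Group labels were exchanged in 10 splits for each pairwise comparison and in 100 drawn splits for each average effect. In the latter each arm kept its labelled majority. Splits mirrored in 1 arm were left out since they compare the arms with each other, which is the interaction. This scheme was chosen after its prediction was written. For the interaction the average effects of line and treatment were fitted on log2 CPM, what remained was exchanged among the 12 libraries in 99 drawn ways, and genes were called with limma-trend. Computation used R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Reads were not analysed here.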

Results

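Gene expression was measured by poly-A RNA sequencing in KP1 cells, a mouse line that the labels give as lung adenocarcinoma. The cells carried either an empty vector (EV) or a vector overexpressing NRF2, the transcription factor that drives antioxidant and detoxification genes and that KEAP1 marks for degradation. Each line was treated for 16 h with DMSO, the solvent, or with 5 nM romidepsin, an inhibitor of class I histone deacetylases (HDACs). The series title puts the study's question as how HDAC inhibition acts on gene regulation and metabolism in tumours with active NRF2. The 2 factors gave 4 groups of 3 libraries, described in the series design as biological replicates: EV with DMSO, NRF2 with DMSO, EV with romidepsin and NRF2 with romidepsin. The labels do not say whether the lines came from more than 1 transduction each, so p-values measure the spread between cultures of these lines.

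The 12 libraries held 16842824 to 28003010 estimated counts each. The most abundant transcripts took little of this depth: the 10 largest genes of a library held 6.66 to 8.35% of its counts. A floor of 3 counts corresponded to 0.107 to 0.178 CPM (counts scaled to a common library size) in a single library; intervals and floors given here cover counting error only. Romidepsin libraries had more genes with at least 1 count, 17930.0 ± 85.8 (SD, n = 3) in EV and 18106 ± 418 in NRF2 cells, against 16675 ± 363 and 16652 ± 362 in the DMSO libraries. Mitochondrially encoded genes took 4.84 to 7.30% of the counts. The highest share, 7.30%, was in replicate 3 of NRF2 cells with DMSO. This library also lay farthest from its replicates: the root mean square log2 distance from the mean of the other 2 libraries was 0.362, against 0.120 to 0.211 in the other 11 libraries. The chi-square per degree of freedom was 36.7 and 46.1 for the pairs with this library and 2.41 to 9.66 for the other pairs of replicates, so no pair agreed within sampling noise and all 12 libraries were counted. In a principal component analysis the first component (78.1% of the variance) separated romidepsin from DMSO and the second separated NRF2 from EV cells.

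The transcript of the overexpressed gene followed the labels. The labels do not say whether the vector carried the mouse sequence or more than the coding part, and a transgene that differs from the mouse transcript would be counted in part, so these levels and folds may not measure its full amount. Nfe2l2, which encodes NRF2 (identifier ENSMUSG00000015839.6; GRCm38 chromosome 2, 75675513 to 75704641, minus strand), measured 102 ± 1.37 CPM in EV cells with DMSO and 305 ± 40.7 CPM in NRF2 cells with DMSO (SD, n = 3), a 2.99-fold difference (log2 1.58 ± 0.07, SE; edgeR adjusted p = 7.2e-11). With romidepsin the levels were 96.3 ± 2.90 and 349 ± 13.8 CPM, a 3.62-fold difference (edgeR adjusted p = 2.8e-11). Romidepsin raised Nfe2l2 slightly in NRF2 cells (log2 0.19 ± 0.07; edgeR adjusted p = 0.016), a call that fails without replicate 1 or 2 of NRF2 cells with DMSO (0.082 each), without replicate 3 of NRF2 cells with romidepsin (0.071) or with the 2 groups fitted alone (0.052). The change in EV cells did not pass the test (log2 -0.08 ± 0.07; edgeR adjusted p = 0.32), and the edgeR test of the difference between the lines gave an adjusted p of 0.073. Keap1 (chromosome 9, 21229730 to 21239361, minus strand) fell with romidepsin by 2.05-fold in EV and 2.01-fold in NRF2 cells (edgeR adjusted p = 6.9e-12 and 5.9e-12). Its NRF2 difference did not pass the test with DMSO or with romidepsin (edgeR adjusted p = 0.21 and 0.093). Trp53 (chromosome 11, 69580359 to 69591873, plus strand) was low in all groups and fell with romidepsin from 12.8 ± 0.495 to 3.57 ± 0.559 CPM in EV cells and from 13.5 ± 1.79 to 2.57 ± 0.254 CPM in NRF2 cells (edgeR adjusted p = 4.6e-10 and 1.5e-11).

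The first comparison asked what NRF2 overexpression changed in untreated cells. Genes of glutathione metabolism and detoxification, the known targets of NRF2, were higher in NRF2 cells with DMSO than in EV cells with DMSO (camera adjusted p = 3.9e-08 and 5.8e-13; adjusted p = 0.11 and 0.0029 with an estimated correlation). They included glutathione S-transferases of the alpha class, which conjugate glutathione to toxic compounds: Gsta1 went from 0.103 ± 0.178 to 55.7 ± 4.28 CPM and Gsta4 from 3.92 ± 0.880 to 50.2 ± 4.25 CPM (SD, n = 3). All 8 counts of Gsta1 in EV cells with DMSO came from replicate 3; without that library the group had no count, so the fold change rests on it. The largest falls included Twist1, a transcription factor of mesenchymal cells, from 18.2 ± 0.348 to 2.58 ± 0.292 CPM. In all, 2608 of the 13502 genes tested were higher and 2287 lower at an edgeR adjusted p under 0.05, of which 518 and 321 changed at least 2-fold. With library size alone as the scaling, lower genes outnumbered higher ones (2894 against 2307).

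Of the detoxification targets of NRF2, 16 of 19 tested genes were higher, 0 lower and 3 not called (17 higher when adjusted over the list alone), with a median log2 fold change of 2.15 (camera adjusted p = 5.8e-13; adjusted p = 0.0029 with an estimated correlation). That median was 2.13 with the genes that had no count in EV cells set at their bound. Gsta2 had no count in EV cells with DMSO and 399 counts in NRF2 cells, at least 129.6-fold higher against a floor of 3 counts over the group. Cbr3, a carbonyl reductase, rose by 44.7-fold (log2 5.48 ± 0.28; edgeR adjusted p = 9.1e-11) and Gsta3 by 26.6-fold (log2 4.73 ± 0.24; edgeR adjusted p = 9.6e-11). Gsta1, Gsta2 and Gsta3 are closely related copies, so how counts were split between them is uncertain. Of the glutathione, thioredoxin and iron targets, 12 of 14 were higher and 0 lower, both over all genes and adjusted over the list alone (camera adjusted p = 3.9e-08; adjusted p = 0.11 with an estimated correlation). They included Blvrb, a biliverdin reductase (4.52-fold, edgeR adjusted p = 3.8e-11), and Osgin1, an oxidative stress-induced growth inhibitor (2.87-fold, 1.7e-12). Others were Hmox1, the haem-degrading enzyme haem oxygenase 1 (2.67-fold, 2.1e-10), and Gclc, the catalytic subunit of the first enzyme of glutathione synthesis (2.11-fold, 7.1e-11).

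Drug efflux transporters were also mostly higher, with 6 of 8 up and 1 down (camera adjusted p = 0.0082; adjusted p = 0.15 with an estimated correlation). Their list shares Abcc1 and Abcc4 with the detoxification list. Abcc2 rose by 26.2-fold (edgeR adjusted p = 1.1e-08) and Abcc3 by 3.09-fold (6.6e-08), whereas Abcg2 fell by 1.84-fold (3.5e-06). Epithelial genes were higher for 7 of 12 and lower for 1 (camera adjusted p = 0.0014; adjusted p = 0.19 with an estimated correlation). They included the keratins Krt7 (1.67-fold, edgeR adjusted p = 2.4e-08) and Krt8 (1.64-fold, 4.5e-09). Ocln, a tight junction protein, was the member that fell (2.70-fold, 0.0034). Mesenchymal genes were lower for 6 of 13 and higher for 3, which did not pass as a group (camera adjusted p = 0.38). The list of genes known to be induced by HDAC inhibitors had 6 members up and 2 down of 10 (8 up when adjusted over the list alone; camera adjusted p = 0.016; adjusted p = 0.14 with an estimated correlation). The members down numbered 1 without replicate 2 or 3 of EV cells with DMSO, any replicate of EV cells with romidepsin, or replicate 1 or 2 of NRF2 cells with romidepsin. The called members included Cdkn1a, a cell cycle inhibitor (2.24-fold, edgeR adjusted p = 1.0e-06), and the transcription factor Klf4 (2.15-fold, 1.4e-06). Histone genes were higher for 6 of 9 (7 adjusted over the list alone; camera adjusted p = 0.034; adjusted p = 0.44 with an estimated correlation). This call also fails without replicate 1 of EV cells with DMSO (0.052) or without replicate 2 of NRF2 cells with DMSO (0.074). Glycolysis genes were higher for 7 of 18 (8 adjusted over the list alone) and nucleotide synthesis genes lower for 6 of 20, and neither passed as a group (camera adjusted p = 0.25 and 0.068). Of the mitochondrially encoded genes 3 of 10 were higher, in a comparison that included the library with the 7.30% mitochondrial share. Without that library 3 were still higher and 1 was lower. The count of higher genes was 1 without replicate 1 or 2 of EV cells with DMSO and 5 without replicate 2 of NRF2 cells with DMSO.

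Among genes with a mean of at least 5 CPM and no overlap between the libraries of the 2 groups, the 6 largest rises were Gsta1 (log2 8.68 ± 0.34), Prl2c2 (4.62 ± 0.21), Tns1 (4.59 ± 0.31), Prl2c3 (3.81 ± 0.10), Gsta4 (3.66 ± 0.10) and Anxa10 (3.63 ± 0.16), each with an edgeR adjusted p of 3.3e-09 or less. Prl2c2 and Prl2c3 are near-identical genes of the prolactin family, proliferins, and their split is uncertain. Tns1 encodes tensin 1, a focal adhesion protein, and Anxa10 an annexin. The 6 largest falls were Smoc2 (-3.73 ± 0.17), Col11a1 (-3.56 ± 0.11), Pcdh18 (-3.38 ± 0.10), Rps6ka6 (-3.05 ± 0.12), Cacna1g (-2.98 ± 0.28) and Twist1 (-2.83 ± 0.14), each with an edgeR adjusted p of 2.6e-07 or less. Smoc2 and Col11a1 encode matrix proteins, Pcdh18 a protocadherin, Rps6ka6 a ribosomal S6 kinase and Cacna1g a calcium channel subunit. Without replicate 3 of NRF2 cells with DMSO, 16 in place of 5 cytosolic ribosomal protein genes were higher, and without replicate 1 of EV cells with DMSO 3 were higher.

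**Figure D1:**
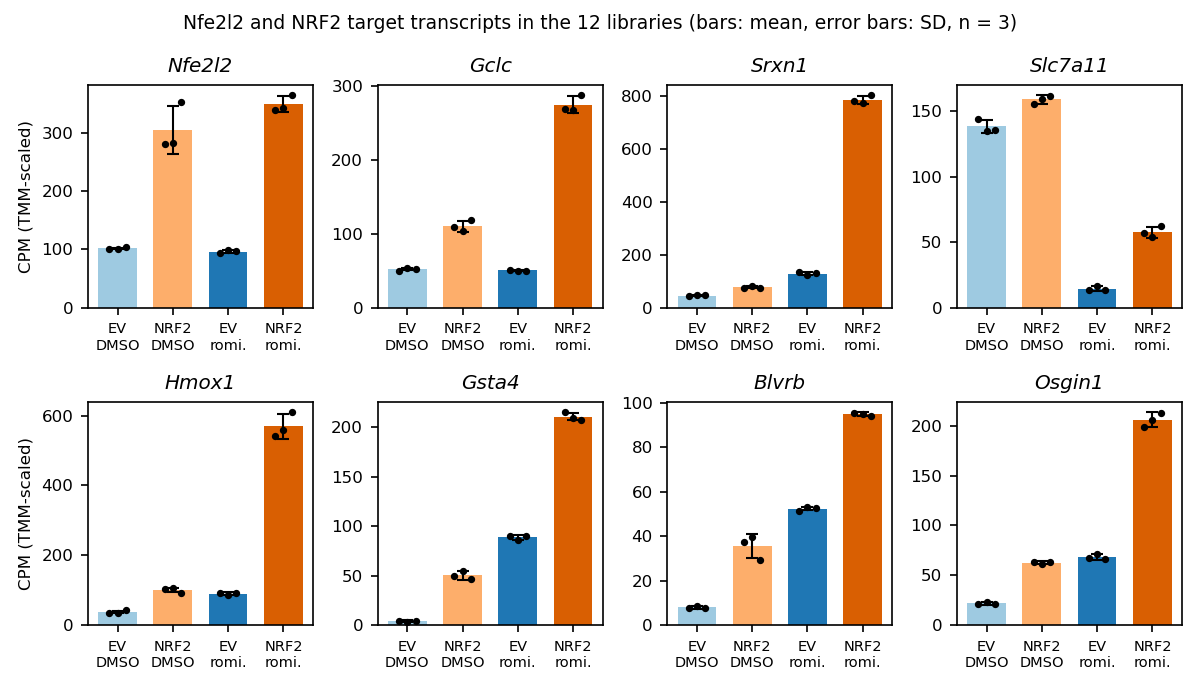
Levels of Nfe2l2 and 7 NRF2 target genes in CPM (vertical axes, from 0) in the 4 groups; bars are means, error bars SD and points the 3 libraries of each group. Nfe2l2 is higher in both NRF2 groups, and Srxn1 is highest in NRF2 cells with romidepsin at 785 CPM against 129 CPM in EV cells with romidepsin.

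The second comparison asked what romidepsin changed in EV cells. Romidepsin lowered genes of the cell cycle, of ribosome production and of serine and one-carbon metabolism and raised neuronal genes, by camera with its preset correlation. With an estimated correlation these calls are lost, with an adjusted p of 0.20 for the cell cycle, 0.22 and 0.50 for ribosome biogenesis and ribosomal proteins, 0.22 for serine and one-carbon metabolism and 0.062 for neuronal genes. Vgf, a neuropeptide precursor, went from 0.424 ± 0.0499 to 142 ± 5.47 CPM (SD, n = 3), a log2 fold change of 8.37 ± 0.10 (edgeR adjusted p = 1.7e-19; chromosome 5, 137026392 to 137033351, plus strand). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 3.78 ± 0.925 to 41.1 ± 1.69 CPM (10.6-fold, edgeR adjusted p = 1.3e-14; chromosome 17, 29090976 to 29100727, plus strand). Slc7a11, the cystine transporter that supplies glutathione synthesis, fell from 138 ± 4.90 to 14.7 ± 1.66 CPM (9.41-fold, 2.4e-16; chromosome 3, 49892526 to 50443614, minus strand). In all, 5281 genes were higher and 5051 lower of 13502, of which 2404 and 1191 changed at least 2-fold. Higher genes outnumbered lower ones by more with upper-quartile factors (5990 against 4392) and with library size alone (6051 against 4332).

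Cell cycle and DNA replication genes fell in 25 of 26 cases and none rose, with a median log2 fold change of -1.07 (camera adjusted p = 1.3e-09; adjusted p = 0.20 with an estimated correlation). The mitotic genes Cdc20 (log2 -1.85 ± 0.07), Plk1 (-1.75 ± 0.06), Aurka (-1.37 ± 0.06) and Ccnb2 (-1.35 ± 0.06) fell most, each with an edgeR adjusted p of 4.5e-13 or less. Cell cycle inhibitors rose in 7 and fell in 2 of 12 cases (camera adjusted p = 0.13). Gadd45g rose by 5.27-fold (edgeR adjusted p = 3.0e-15) and Cdkn2b fell by 1.87-fold (1.9e-11). MYC and ribosome biogenesis genes fell in 15 of 18 cases (camera adjusted p = 3.3e-05; adjusted p = 0.22 with an estimated correlation). They included Dkc1 (log2 -1.43 ± 0.08) and the nucleolar protein gene Nop56 (-1.34 ± 0.05), and Bop1 rose (0.55 ± 0.07). Cytosolic ribosomal protein genes fell in 26 of 30 cases with a median of -0.48 (camera adjusted p = 1.2e-04; adjusted p = 0.50 with an estimated correlation), and their pseudogene copies make single members uncertain. Nucleotide synthesis genes fell in 19 of 20 cases (camera adjusted p = 9.5e-05; adjusted p = 0.23 with an estimated correlation). Among these, thymidine kinase Tk1 fell by 3.18-fold (edgeR adjusted p = 7.2e-13) and ribonucleotide reductase Rrm2 by 2.61-fold (1.4e-12), whereas Impdh1, of guanine nucleotide synthesis, rose (log2 1.32 ± 0.06; 5.3e-13).

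Serine and one-carbon metabolism genes fell in 12 of 14 cases with 1 up, or none up without replicate 3 of EV cells with DMSO or replicate 1 or 2 of EV cells with romidepsin (camera adjusted p = 1.3e-04; adjusted p = 0.22 with an estimated correlation). The mitochondrial folate enzymes Mthfd1l, Shmt2 and Mthfd2 fell by 4.78-, 3.06- and 2.87-fold (edgeR adjusted p = 2.1e-15, 2.2e-14 and 1.9e-13). Of the ATF4 and integrated stress response genes 10 of 16 fell and 4 rose (camera adjusted p = 0.058). Trib3 fell by 5.36-fold and Atf3 rose by 5.17-fold (edgeR adjusted p = 3.1e-07 and 1.1e-10). Genes of glutamine, glutamate and aspartate use and transport fell in 13 and rose in 6 of 20 cases (camera adjusted p = 0.081): the glycine transporter gene Slc6a9 fell by 5.38-fold (3.5e-14) and glutamine synthetase, Glul, rose by 2.71-fold (1.8e-14). Genes of the tricarboxylic acid cycle had 10 up and 4 down of 19, with pyruvate carboxylase, Pcx, up by 6.04-fold (edgeR adjusted p = 2.2e-15), and glycolysis genes had 12 up and 6 down of 18 (camera adjusted p = 0.13 and 0.12). The pentose phosphate and NADPH genes had 4 up and 5 down of 9, with Taldo1 up by 2.11-fold, and the cholesterol synthesis genes 8 up and 2 down of 21, with Hsd17b7 up by 3.43-fold; neither list passed (camera adjusted p = 0.82 and 0.19). The cholesterol genes down numbered 4 without replicate 3 of EV cells with DMSO, 5 without replicate 3 of NRF2 cells with romidepsin, and 1 without any of the other 5 EV libraries.

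Genes known to be induced by HDAC inhibitors rose in 8 of 10 cases and fell in 1, with a median of 2.07 (camera adjusted p = 7.3e-04; adjusted p = 0.062 with an estimated correlation). They included the linker histone gene H1f0 (4.47-fold), the actin-binding gelsolin gene Gsn (4.49-fold) and the neuronal tubulin gene Tubb3 (5.18-fold), with edgeR adjusted p of 3.4e-10 or less. Of the HDACs, acetyltransferases and BET readers 17 of 23 fell and 5 rose (camera adjusted p = 0.031; adjusted p = 0.20 with an estimated correlation): Hdac7 fell by 3.71-fold and Hdac11 rose by 3.24-fold (edgeR adjusted p = 3.1e-14 and 8.4e-14). Histone genes had 5 up and 3 down of 9 (camera adjusted p = 0.22). The count of falls was 1 under 4 other scalings or without any of 4 libraries (replicates 2 and 3 of EV cells with DMSO, replicates 1 and 2 of EV cells with romidepsin). Neuronal genes rose in 12 of 15 tested cases, of 27 fixed, and fell in 1 (camera adjusted p = 8.5e-04; adjusted p = 0.062 with an estimated correlation); L1cam rose by 37.6-fold and Syn1 by 12.2-fold (edgeR adjusted p = 9.3e-14 and 4.3e-15), and Bdnf fell by 1.73-fold (4.0e-09). Epithelial genes rose in 10 of 12 cases (camera adjusted p = 0.0053; adjusted p = 0.22 with an estimated correlation). Epcam had 2 counts over the EV group with DMSO and 229 with romidepsin, a ratio of 111 (95% counting interval 30.3 to 918), whereas Cdh1, which encodes E-cadherin, fell by 1.43-fold (edgeR adjusted p = 5.7e-09). Mesenchymal genes fell in 8 and rose in 3 of 13 cases (camera adjusted p = 0.13). Hmga2 fell by 3.73-fold and the collagen gene Col1a1 rose by 11.3-fold.

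Interferon-stimulated genes rose in 12 of 13 tested cases, of 20 fixed, and none fell (camera adjusted p = 0.0034; adjusted p = 0.080 with an estimated correlation). The interferon regulator Irf7 went up from 0.107 ± 0.0475 to 8.67 ± 0.184 CPM (edgeR adjusted p = 9.8e-13). The share that rose is partly fixed by the filter, and this list was not compared with genes of the same DMSO level. Genes of antigen presentation by MHC class I rose in 6 and fell in 2 of 8 cases (camera adjusted p = 0.12): H2-K1 rose by 13.5-fold and the peptide-trimming Erap1 fell by 5.09-fold (edgeR adjusted p = 1.8e-15 and 2.9e-12). Of 15 blood and endothelium markers 7 could be tested and 6 rose, with 1 lower when adjusted over the list alone. Their median log2 fold change was 4.33, and as a list they did not pass (camera adjusted p = 0.0502). Markers that were silent in all groups were not tested, so the share that rose is partly fixed by the filter. The lysosomal gene Cd68 measured 3.27 ± 0.636 CPM with DMSO and 49.6 ± 2.36 CPM with romidepsin. The globin gene Hba-a1, which has a near-identical copy, measured 0.0663 ± 0.0836 and 5.58 ± 0.991 CPM. Fibroblast markers had 1 up of 2 tested and lung alveolar and airway genes 3 up and 1 down of 5 tested (camera adjusted p = 0.47 and 0.49). Of the pro-death BCL2 family genes 3 rose and 2 fell of 8, with Bcl2l11, which encodes BIM, up by 2.58-fold (edgeR adjusted p = 3.5e-13). Of the pro-survival members 3 fell and 1 rose of 4, with Bcl2l1 down by 1.49-fold (5.4e-09); neither list passed (camera adjusted p = 0.69 and 0.35). Drug efflux transporters had 3 up and 4 down of 8, including Abcg2 (2.80-fold up) and Abcb1b (2.55-fold down; its copy Abcb1a makes the split uncertain). The list median of 0.02 and the downward camera direction differed in sign (camera adjusted p = 0.90). Of the mitochondrially encoded genes 3 of 10 were higher, 2 adjusted over the list alone (camera adjusted p = 0.47).

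The targets of NRF2 moved in both directions. Detoxification genes rose in 14 of 19 cases and fell in 1 (camera adjusted p = 0.0035; adjusted p = 0.12 with an estimated correlation). Gsta4 rose by 22.2-fold and the epoxide hydrolase gene Ephx1 by 13.4-fold (edgeR adjusted p = 2.7e-16 and 5.5e-14), and Abcc1 fell by 1.33-fold (7.1e-08). Glutathione, thioredoxin and iron genes rose in 9 and fell in 4 of 14 cases (camera adjusted p = 0.081). Blvrb rose by 6.65-fold and Slc7a11 fell most. Among the genes chosen by size, Slc17a7, a vesicular glutamate transporter, had 1 count over the EV group with DMSO and 717 with romidepsin, a ratio of 692 (95% counting interval 124 to 27376). The same ratio was 511 (141 to 4226) for Cnn1, calponin of smooth muscle, 415 (74.1 to 16433) for Dpysl5, a neuronal gene, and 283 (77.9 to 2341) for Slc2a4, the insulin-responsive glucose transporter. Vgf and Stac2 (log2 8.19 ± 0.20; edgeR adjusted p = 6.1e-16) completed the 6 largest rises. The 6 largest falls were Atoh8 (log2 -3.92 ± 0.09), Bend3 (-3.66 ± 0.10), Rcbtb2 (-3.49 ± 0.13), Qrfp (-3.30 ± 0.14), Slc7a11 (-3.23 ± 0.07) and Clcf1 (-3.15 ± 0.07), each with an edgeR adjusted p of 1.1e-11 or less. Atoh8 is a transcription factor, Bend3 a DNA-binding repressor, Qrfp a neuropeptide and Clcf1 a cytokine. Upper-quartile factors shifted the median log2 fold change of all genes by 0.11 in EV and 0.11 in NRF2 cells, and library size alone by 0.12 and 0.14, so changes are relative to the TMM scaling.

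**Figure D2:**
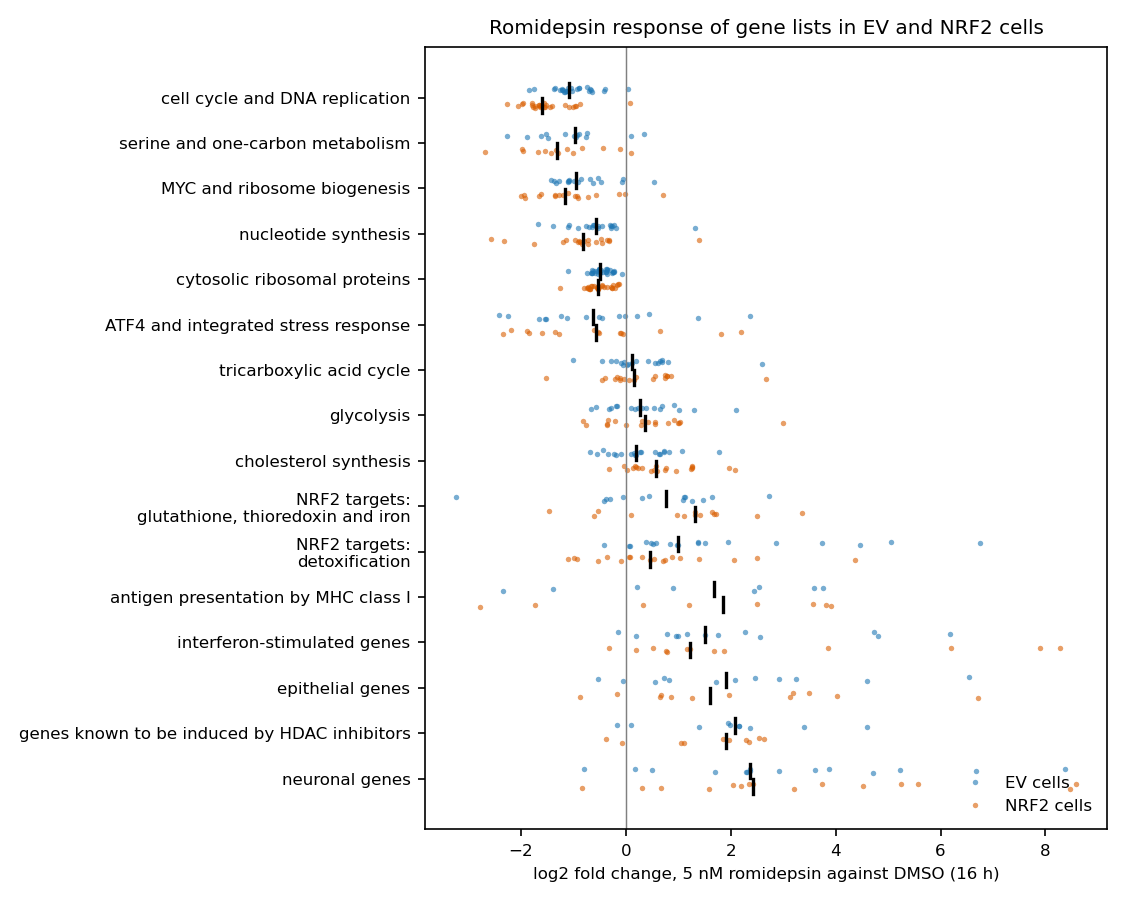
Log2 fold change with romidepsin against DMSO (horizontal axis) for the tested members of 16 gene lists, in EV cells (blue) and NRF2 cells (orange); each point is a gene and black bars are list medians. The cell cycle list has medians of -1.07 and -1.60, and the neuronal list 2.37 and 2.42.

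The third comparison asked what romidepsin changed in NRF2 cells. The cell cycle, ribosome biogenesis, ribosomal protein and one-carbon lists fell again by camera with its preset correlation, calls that are lost with an estimated one (adjusted p = 0.22, 0.22, 0.52 and 0.22 with an estimated correlation). Vgf went from 0.465 ± 0.0764 to 164 ± 9.37 CPM (SD, n = 3). Of the glutathione, thioredoxin and iron targets of NRF2 10 rose and 3 fell of 14 (camera adjusted p = 0.0061; adjusted p = 0.25 with an estimated correlation). Srxn1, which encodes sulfiredoxin (chromosome 2, 152105516 to 152111376, plus strand), went from 76.8 ± 3.57 to 785 ± 15.5 CPM, and Hmox1 from 100.1 ± 6.52 to 569 ± 35.3 CPM, whereas Slc7a11 fell by 2.76-fold (edgeR adjusted p = 3.9e-13). In all, 5471 genes were higher and 5309 lower of 13502, of which 2599 and 1703 changed at least 2-fold. The counts were 6080 and 4729 with upper-quartile factors and 6256 and 4561 with library size alone.

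Cell cycle and DNA replication genes fell in 25 of 26 cases, with a median of -1.60 (camera adjusted p = 1.8e-10; adjusted p = 0.22 with an estimated correlation). They included Cdc20 (log2 -2.26 ± 0.07), Plk1 (-2.06 ± 0.06), Aurka (-1.99 ± 0.06) and the replication helicase gene Mcm3 (-1.95 ± 0.06). Nucleotide synthesis genes fell in 19 of 20 cases (camera adjusted p = 2.0e-05; adjusted p = 0.22 with an estimated correlation). Rrm2 fell by 5.96-fold and Tk1 by 4.99-fold (edgeR adjusted p = 7.8e-16 and 1.1e-14). Serine and one-carbon genes fell in 12 of 14 cases (camera adjusted p = 1.8e-04; adjusted p = 0.22 with an estimated correlation). Mthfd1l fell by 6.44-fold and Gldc, of glycine cleavage, by 3.93-fold. MYC and ribosome biogenesis genes fell in 16 of 18 cases, with Nop56 down by 4.01-fold (camera adjusted p = 2.0e-05; adjusted p = 0.22 with an estimated correlation). Cytosolic ribosomal protein genes fell in 26 of 30 cases (camera adjusted p = 2.1e-04; adjusted p = 0.52 with an estimated correlation). ATF4 and integrated stress response genes fell in 10 and rose in 3 of 16 cases, with Atf4 itself down by 3.70-fold (edgeR adjusted p = 3.4e-12). Glutamine, glutamate and aspartate genes fell in 11 and rose in 6 of 20 cases (camera adjusted p of the ATF4 and glutamine lists = 0.073 and 0.23). Genes of the tricarboxylic acid cycle had 10 up and 6 down of 19 (3 down with upper-quartile factors or library size alone). Glycolysis had 11 up and 6 down of 18 and pentose phosphate and NADPH 5 up and 4 down of 9. None of these 3 lists passed (camera adjusted p = 0.23, 0.15 and 0.69). Aldoc, of glycolysis, rose by 7.96-fold, Pcx by 6.34-fold and G6pdx, which feeds the pentose phosphate pathway, by 1.66-fold (edgeR adjusted p = 1.3e-13, 4.2e-16 and 2.6e-11). Cholesterol synthesis genes rose in 13 and fell in 1 of 21 cases (camera adjusted p = 0.011; adjusted p = 0.56 with an estimated correlation). Hsd17b7 rose by 4.24-fold and the squalene epoxidase gene Sqle by 2.41-fold.

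Neuronal genes rose in 13 of 15 cases and epithelial genes in 10 of 12 (camera adjusted p = 6.9e-04 and 0.011; adjusted p = 0.11 and 0.23 with an estimated correlation). Syp, a synaptic vesicle gene, rose by 13.3-fold, Epcam by 104-fold and the transcription factor Elf3 by 9.11-fold, and Cdh1 fell by 1.84-fold (edgeR adjusted p of 3.1e-12 or less for these genes). Epcam had only 4 counts over the DMSO group, so the size of its fold is uncertain. Interferon-stimulated genes rose in 11 (12 adjusted over the list alone) and fell in 1 of 13 cases (none fell without replicate 3 of either NRF2 group), and genes known to be induced by HDAC inhibitors in 8 and 1 of 10 (camera adjusted p = 0.0083 and 0.0057; adjusted p = 0.13 and 0.13 with an estimated correlation). Irf7 rose by 73.7-fold and Txnip, an inhibitor of thioredoxin, by 4.87-fold (edgeR adjusted p = 2.1e-13 and 1.7e-15). Antigen presentation genes had 6 up and 2 down of 8, cell cycle inhibitors 8 up and 2 down of 12, histone genes 4 up and 2 down of 9, and mesenchymal genes 3 up and 10 down of 13, and none of the 4 lists passed (camera adjusted p = 0.10, 0.080, 0.23 and 0.11). HDACs, acetyltransferases and BET readers fell in 18 of 23 cases (camera adjusted p = 0.032; adjusted p = 0.22 with an estimated correlation). Hdac11 rose by 4.21-fold. Blood and endothelium markers rose in 7 of 7 tested cases (camera adjusted p = 0.029; adjusted p = 0.22 with an estimated correlation), with Cd68 at 68.4 ± 1.89 CPM, and fibroblast markers in 2 of 2, or 1 without replicate 2 of the DMSO group (camera adjusted p = 0.31). Of the blood and endothelium markers 15 were fixed, and those silent in all groups were not tested. The share that rose is thus partly fixed by the filter, as it is for neuronal and interferon-stimulated genes. Lung alveolar and airway genes had 3 up and 1 down of 5 (camera adjusted p = 0.55). Pro-death BCL2 genes had 4 up and 2 down of 8 and pro-survival members 0 up and 3 down of 4 (camera adjusted p = 0.34 and 0.23). Bcl2l11 rose by 2.81-fold. Without replicate 3 of the DMSO group 1 pro-survival member was higher. Drug efflux transporters had 3 up and 5 down of 8, with Abcb1b down by 4.17-fold (camera adjusted p = 0.34). Of the mitochondrially encoded genes 3 of 10 were lower and 0 higher, with 1 lower adjusted over the list alone (camera adjusted p = 0.68). The list median of -0.11 turned positive with upper-quartile factors, with library size alone (0.03) and without replicate 3 of the DMSO group (0.08). Without that library 3 members were also higher, and without replicate 1 or 2 of the romidepsin group 1 was lower.

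Glutathione, thioredoxin and iron targets of NRF2 rose in 10 and fell in 3 of 14 cases (camera adjusted p = 0.0061; adjusted p = 0.25 with an estimated correlation). Srxn1 rose by 10.2-fold, Hmox1 by 5.68-fold and the ferritin heavy chain gene Fth1 by 3.22-fold, and Slc7a11 fell by 2.76-fold (edgeR adjusted p = 1.7e-18, 5.6e-15, 2.6e-14 and 3.9e-13). Detoxification targets rose in 11 and fell in 5 of 19 cases (camera adjusted p = 0.17). Gsta4 rose by 4.19-fold and Gsta3 fell by 2.14-fold. The 6 largest rises by the rule of size were Slc17a7 (log2 8.67 ± 0.23), Vgf (8.46 ± 0.10), Nxph4, a neurexophilin, Cnn1, Cd248, endosialin (7.68 ± 0.22), and Stac2 (7.47 ± 0.15), with edgeR adjusted p of 2.9e-14 or less. Slc17a7 had only 4 counts over the DMSO group, so the size of its fold is uncertain beyond its SE. Nxph4 had 2 counts over the DMSO group and 878 with romidepsin, a ratio of 411 (95% counting interval 114 to 3403). Cnn1 had 3 and 1138 counts, a ratio of 356 (121 to 1726). The 6 largest falls were Prl2c2 (log2 -5.34 ± 0.23), Rcbtb2 (-4.11 ± 0.13), Prl2c3 (-4.10 ± 0.10), Clcf1 (-4.10 ± 0.07), Trim65 (-3.89 ± 0.16) and Selp, the adhesion molecule P-selectin (-3.86 ± 0.06), with edgeR adjusted p of 6.5e-11 or less.

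The romidepsin responses of the lines were alike in direction. Across the 13502 genes, which are not independent replicates, the log2 fold changes in EV and NRF2 cells had a Pearson r of 0.921 and a Spearman rho of 0.931, and 90.7% of genes had the same sign. The lines share no library in this comparison. There were 4821 genes higher in both lines, where independent lists would share 2139.9, and 4665 lower in both, where 1986 would be shared, and 64 genes were called in opposite directions.

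The fourth comparison asked what NRF2 overexpression changed in the presence of romidepsin. Targets of NRF2 were higher in NRF2 cells, among them Gsta1, at 0.526 ± 0.352 CPM in EV and 28.1 ± 3.34 CPM in NRF2 cells (SD, n = 3), and by Hmox1, at 90.0 ± 3.30 and 569 ± 35.3 CPM. Cell cycle genes were lower in NRF2 cells by camera with its preset correlation (adjusted p = 0.17 with an estimated correlation), for example Top2a, which encodes topoisomerase 2 alpha, at 404 ± 17.2 against 236 ± 2.08 CPM. In all, 3107 genes were higher and 3026 lower of 13502, of which 554 and 199 changed at least 2-fold. With library size alone lower genes outnumbered higher ones (3233 against 2914), and with upper-quartile factors they did so by less (3087 against 3055).

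Detoxification targets were higher in 18 and lower in 1 of 19 cases, with none lower without replicate 1 or 2 of the EV or replicate 3 of the NRF2 group (camera adjusted p = 1.6e-10; adjusted p = 0.0095 with an estimated correlation). Glutathione, thioredoxin and iron targets were higher in 13 and lower in 1 of 14 (camera adjusted p = 6.4e-13; adjusted p = 0.030 with an estimated correlation). They included Srxn1 (6.10-fold), Gclc (5.44-fold) and Slc7a11 (3.92-fold), with edgeR adjusted p of 2.9e-12 or less, and Txn1, thioredoxin, was the lower member (log2 -0.31 ± 0.07; 0.0021). Cell cycle genes were lower in 25 of 26 cases with a median of -0.52 (camera adjusted p = 6.5e-14; adjusted p = 0.17 with an estimated correlation). They included Ccne2 (log2 -0.82 ± 0.09), Mcm3 (-0.81 ± 0.06), Top2a (-0.77 ± 0.05) and Cdk1 (-0.75 ± 0.06). Nucleotide synthesis genes were lower in 18 of 20 cases (camera adjusted p = 2.5e-08; adjusted p = 0.21 with an estimated correlation), with Rrm2 at log2 -0.99 ± 0.07 (edgeR adjusted p = 4.8e-09). MYC and ribosome biogenesis genes were lower in 12 of 18 cases and serine and one-carbon genes in 7 of 14 (10 adjusted over the list alone; camera adjusted p = 1.7e-04 and 0.0029; adjusted p = 0.43 and 0.46 with an estimated correlation). Epithelial genes were higher in 8 of 12 cases, 9 adjusted over the list alone (camera adjusted p = 0.0012; adjusted p = 0.21 with an estimated correlation). Krt7 was 1.79-fold higher. The 6 largest rises were Gsta1 (log2 5.74 ± 0.29), Sprr2h, a cornified envelope gene (3.60 ± 0.14), Trf, transferrin (3.51 ± 0.32), the tetraspanins Cd81 (2.75 ± 0.09) and Cd82 (2.75 ± 0.12), and Hmox1 (2.66 ± 0.07), with edgeR adjusted p of 3.4e-06 or less. The 6 largest falls were Pcdh18 (log2 -3.05 ± 0.13), the matrix gene Tnc, tenascin C (-3.02 ± 0.06), Smoc2 (-2.45 ± 0.18), Rps6ka6 (-2.38 ± 0.11), Twist1 (-2.37 ± 0.16) and Lhfp (-2.35 ± 0.08), with edgeR adjusted p of 1.3e-08 or less. Without replicate 3 of NRF2 cells with DMSO, which belongs to neither group compared and enters through the joint fit, 11 serine and one-carbon genes were lower.

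The NRF2 effects with DMSO and with romidepsin had a Pearson r of 0.604 and a Spearman rho of 0.535 across genes, and 70.2% of genes had the same sign. There were 1685 genes higher in NRF2 cells under both treatments, where independent lists would share 600.1, and 1366 lower under both, where 513 would be shared, and 170 genes were called in opposite directions.

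The interaction asked whether the romidepsin response differed between NRF2 and EV cells, or equally whether the NRF2 difference changed with romidepsin. Cell cycle and DNA replication genes fell further in NRF2 cells: Mcm3 went from 177 ± 11.2 to 77.8 ± 2.28 CPM in EV and from 172 ± 3.80 to 44.4 ± 2.27 CPM in NRF2 cells (SD, n = 3). The targets of NRF2 parted. The glutathione genes Gclc, Srxn1 and Slc7a11 were relatively higher in NRF2 cells with romidepsin, and detoxification genes such as Gsta4 rose less in NRF2 than in EV cells. These list calls used the preset correlation of camera (adjusted p = 0.071, 0.071 and 0.071 for the cell cycle, glutathione and detoxification lists with an estimated correlation). In all, 747 genes had a higher and 1380 a lower response in NRF2 cells by edgeR, of which 117 and 130 differed at least 2-fold.

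Of the cell cycle genes 24 of 26 had a lower response in NRF2 cells and none a higher one, with a median of -0.48 (camera adjusted p = 5.0e-20; adjusted p = 0.071 with an estimated correlation). They included Mcm3 (log2 -0.76 ± 0.08), Cdc6 (-0.76 ± 0.08), Mki67 (-0.75 ± 0.15) and Ccne2 (-0.74 ± 0.12), with edgeR adjusted p of 0.0051 or less. Nucleotide synthesis genes had a lower response in 9 of 20 cases (10 adjusted over the list alone), led by Rrm2 (-1.19 ± 0.09; edgeR adjusted p = 2.1e-07), and MYC and ribosome biogenesis genes in 11 of 18 (12 adjusted over the list alone), led by Nop56 (-0.67 ± 0.07; 5.2e-06). The MYC count was 7 without replicate 1 of EV cells with DMSO, replicate 2 of EV cells with romidepsin or replicate 3 of NRF2 cells with romidepsin. Both lists passed with the preset correlation (camera adjusted p = 2.6e-06 and 2.2e-05; adjusted p = 0.24 and 0.27 with an estimated correlation). Serine and one-carbon genes had 5 lower and 1 higher responses of 14, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.027; adjusted p = 0.52 with an estimated correlation). This call fails without replicate 1 (camera adjusted p = 0.058) or 2 (0.070) of NRF2 cells with DMSO and without replicate 2 of NRF2 cells with romidepsin (0.053). Without replicate 1 of the latter group 2 serine genes were higher. Glutathione, thioredoxin and iron targets had 9 higher and 1 lower responses of 14, 10 and 2 adjusted over the list alone, with a median of 0.55 (camera adjusted p = 6.7e-09; adjusted p = 0.071 with an estimated correlation). Srxn1 (1.87 ± 0.07), Slc7a11 (1.77 ± 0.09) and Gclc (1.37 ± 0.08) were higher and Blvrb (-1.32 ± 0.12) lower, with edgeR adjusted p of 3.9e-06 or less. Detoxification targets had 10 lower and 0 higher responses of 19, with a median of -0.92, or -0.74 with genes without a count set at their bound. The median was -0.12 over the 11 members with at least 1 CPM in each of the 4 groups, 5 of which had a lower response. The list passed with the preset correlation (camera adjusted p = 1.4e-04; adjusted p = 0.071 with an estimated correlation). Gsta4 (-2.41 ± 0.12) and Cbr3 (-2.79 ± 0.43) had edgeR adjusted p of 2.3e-09 and 2.9e-04. Cholesterol synthesis genes had 3 higher and 0 lower responses of 21 (camera adjusted p = 9.1e-06; adjusted p = 0.52 with an estimated correlation). They included Mvd (0.60 ± 0.12) and Mvk (0.51 ± 0.11). Drug efflux transporters had 4 lower and 1 higher responses of 8 (camera adjusted p = 0.020; adjusted p = 0.24 with an estimated correlation), including Abcb1a (-0.91 ± 0.12). Cholesterol genes with a higher response numbered 6 without replicate 3 of EV cells with DMSO and 10 without replicate 1 of NRF2 cells with romidepsin. The higher efflux response was called in 3 of the 12 fits that leave out a library.

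By the rule of size, the 6 highest interactions were Cacna1g (log2 2.98 ± 0.30), Enpp2, autotaxin (2.29 ± 0.21), Srxn1, Vdr, the vitamin D receptor (1.82 ± 0.32), the creatine kinase gene Ckb (1.79 ± 0.16) and Slc7a11, with edgeR adjusted p of 0.00084 or less. The 6 lowest were Prl2c2 (-3.17 ± 0.61; edgeR adjusted p = 0.0037), Gsta1 (-2.94 ± 0.83; 0.033; 0.051 to 0.12 without any of 5 libraries), Prl2c3 (-2.82 ± 0.19; 7.2e-08), Gsta4, Tns1 (-2.03 ± 0.41; 0.0028) and S100a7a, an S100 calcium-binding gene (-2.03 ± 0.18; 1.1e-06). The count of higher interactions was 465 without replicate 2 of EV cells with romidepsin, and the count of lower ones 2127 without replicate 3 of NRF2 cells with DMSO. Without the latter, lower responses numbered 16 of 30 for cytosolic ribosomal proteins, against 1 with all libraries, and 5 each for ATF4 and integrated stress response and for glycolysis genes, against 1 each. They also numbered 14 for nucleotide synthesis, 8 for serine and one-carbon genes and 3 for glutathione, thioredoxin and iron targets, which numbered 2 without replicate 1 of NRF2 cells with romidepsin. The Gsta1 call fails without replicate 1 or 2 of EV cells with DMSO, replicate 3 of NRF2 cells with DMSO, replicate 1 of EV cells with romidepsin or replicate 3 of NRF2 cells with romidepsin, and its size rests on replicate 3 of EV cells with DMSO, the 1 library of that group with counts. It also fails with the replicate block (edgeR adjusted p = 0.051), with no filter (0.11) and with limma-trend on the deposited normalized values (0.054).

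**Figure D3:**
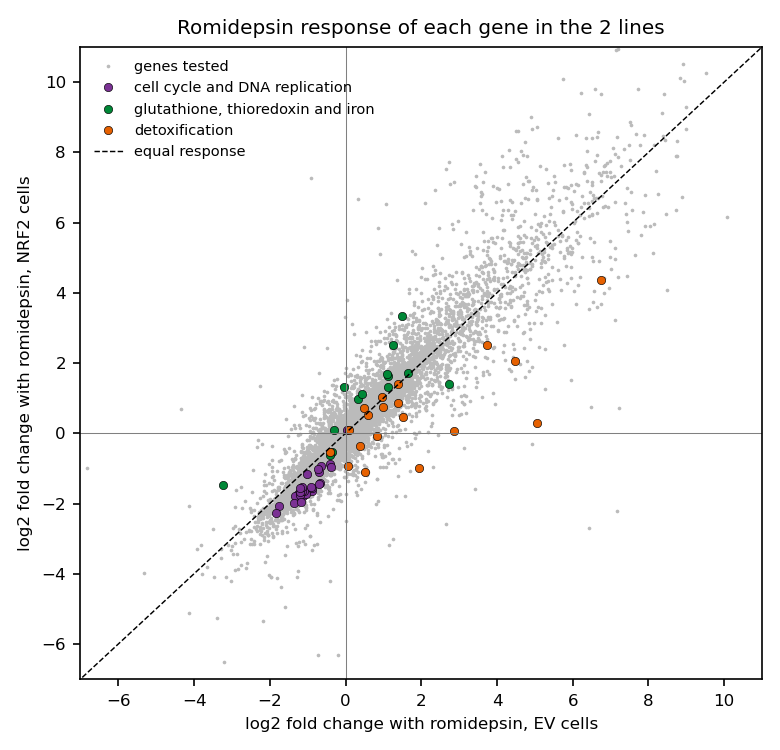
Log2 fold change with romidepsin in EV cells (horizontal axis) against that in NRF2 cells (vertical axis), 1 point per gene tested (7 genes lie outside the axes), with 3 gene lists in colour and a dashed line of equal response. Most cell cycle genes (purple) lie below the line, most detoxification genes (orange) lie below it, and most glutathione, thioredoxin and iron genes (green) lie above it.

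Averaged over treatments, 3315 genes were higher and 3534 lower in NRF2 than in EV cells, and averaged over lines, 5776 were higher and 5532 lower with romidepsin (edgeR). These averages and the interaction are orthogonal in this design. The genes higher with NRF2, among them Gclc and Hmox1, rose with romidepsin by a median log2 of 0.32 (camera p = 2.1e-06; p = 0.00059 with an estimated correlation), with 1968 higher and 946 lower. The genes lower with NRF2, among them Twist1 and Tnc, fell by a median of 0.39 (camera p = 9.2e-12; p = 0.00012 with an estimated correlation), with 876 higher and 2243 lower. In the interaction the medians were -0.04 for the former (camera p = 0.30; p = 0.26 with an estimated correlation) and -0.06 for the latter (camera p = 0.015; p = 0.042 with an estimated correlation).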

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

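The tests on genes near the detection floor, on paralogs, on red blood cells, on detected genes at equal totals and on exchanged libraries for the interaction were chosen after the results were seen. The response to romidepsin differed between NRF2 and EV cells by the interaction test of edgeR: 747 genes had a higher and 1380 a lower response in NRF2 cells. With the average effects of line and treatment set apart, the labelled assignment of the 12 libraries called 2153 genes by limma-trend. The highest of the other 99 drawn assignments called 41. This argues against chance differences between these cultures for the interaction, though the exchange treated all libraries as equally variable. The labelled split also called the most genes for the average NRF2 effect (6849 against 2955) and the average romidepsin effect (11308 against 7623). In each case 1 of 100 splits was as large. Those splits kept the labelled majority in each arm, so this share is not over all possible splits and does not exclude chance. Exchanging cultures cannot address chance differences between the derived lines. For the 4 pairwise comparisons the 10 splits are too few for a share under 0.05. Fitted on 6 libraries alone, these called 3654 genes for NRF2 with DMSO, 10459 and 10292 for romidepsin in EV and NRF2 cells, and 7618 for NRF2 with romidepsin, and 0 in the highest other split of each.

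Lists that differed between the lines by camera had these median interactions on the log2 scale: glutathione, thioredoxin and iron 0.55, detoxification -0.92, serine and one-carbon metabolism -0.24, cholesterol synthesis 0.39, nucleotide synthesis -0.19, cell cycle and DNA replication -0.48, MYC and ribosome biogenesis -0.25 and drug efflux -0.21. None of these calls held with an estimated correlation. The genes with the most negative interactions by edgeR were Prl2c2 (-3.17), Gsta1 (-2.94), Prl2c3 (-2.82), Gsta4 (-2.41), Tns1 (-2.03) and S100a7a (-2.03). Those with the most positive were Cacna1g (2.98), Enpp2 (2.29), Srxn1 (1.87), Vdr (1.82), Ckb (1.79) and Slc7a11 (1.77). The Gsta1 call fails without any of 5 single libraries (replicates 1 and 2 of EV cells with DMSO, replicate 3 of NRF2 cells with DMSO, replicate 1 of EV cells with romidepsin and replicate 3 of NRF2 cells with romidepsin), with an adjusted p of 0.051 to 0.12. It also fails with the replicate number as a block (0.051), with no filter (0.11) and with limma-trend on the deposited normalized values (0.054).

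Cell cycle and DNA replication genes fell further with romidepsin in NRF2 than in EV cells. This list call of camera with its preset correlation is lost with an estimated one (adjusted p = 0.071). Without the NRF2 library with DMSO that stood apart 24 of 26 members were still called, with every library thinned to the same total 24 were called, and the median stayed at or below -0.46 under 4 other scalings, which argues against that library, depth and scaling. A larger response of NRF2 cells at every gene that fell would place the list level with genes matched on EV response and mean expression. Its median of -1.60 lay lower, at percentile 0 of 10000 random lists so matched (median -1.16, lower 95% bound -1.30). The random genes were drawn independently, so this percentile takes no account of members that move together and does not exclude that explanation. Open explanations, as untested, are an effect of NRF2 itself, a different share of cycling cells or growth rate and differences between derived lines other than NRF2, since the labels do not say whether transductions were independent.

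Under romidepsin the NRF2 difference narrowed for detoxification genes and widened for glutathione and thioredoxin genes. Without the library that stood apart the medians of the lists still differed by 1.44, against 1.47 with all libraries. Over the members of both lists with at least 1 CPM in each of the 4 groups, the medians differed by 0.675 with all libraries. Genes near the detection floor do not account for 5 of the 11 members with at least 1 CPM in each of the 4 groups. Those 5 had a called negative interaction. Outside the glutathione transferase families 6 of 11 members had one, which reads shared within those families do not account for. Reads shared between related genes outside those families, such as Cbr1 and Cbr3, were not tested. Whether the floor adds to the list's median of -0.92 stays open. That median was -0.12 over the 11 members with at least 1 CPM in each group. The other 8, however, included the members that NRF2 raised most, Gsta1 and Cbr3 among them (log2 8.68 ± 0.34 and 5.48 ± 0.28 with DMSO, against 3.66 ± 0.10 for Gsta4). Differences between the derived lines stay open, as untested. A limit to how far already high genes can rise would not lower a gene. With romidepsin 5 detoxification targets fell in NRF2 cells and 11 rose, so such a limit, also untested, stays open only for targets that did not fall.

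Markers of neurons and of blood and endothelium rose with romidepsin in both lines, although the blood and endothelium list as a whole did not pass in EV cells (camera adjusted p = 0.0502). With an estimated correlation no list call held (adjusted p = 0.062 in EV and 0.11 in NRF2 cells for neurons, and 0.22 in NRF2 cells for blood and endothelium). Red blood cells would bring both of their abundant globin transcripts, but Hbb-bs was at 0.236% of Hba-a1 (0.0190 against 8.07 CPM) in NRF2 cells with romidepsin, which argues against them for Hba-a1; the other markers that rose come from several cell types, led by Cd68 (68.4 CPM) and Lyz2 (3.42 CPM), and whether such cells were present stays open. Depth is argued against by 1401 more genes detected with romidepsin at equal totals (17674 against 16273 on average). A rise of weakly expressed genes in general may account for the blood and endothelium markers. Their median of 4.15 lay at percentile 89.4 of lists of tested genes matched on the DMSO level (median 2.96). The neuronal median of 3.32 was higher than that of such lists (0.96, percentile 99.99). The random genes were drawn independently, so the percentiles take no account of members that move together. A general rise is thus not excluded for the neuronal markers. Averaged over lines, 1147 of 1374 tested genes under 0.5 CPM with DMSO were higher and 14 lower, shares that are partly fixed by the filter. For the neuronal markers a release by HDAC inhibition beyond genes of the same DMSO level and a neuronal cell fraction also stay open, as untested.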

How the results depend on the processing

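All alternatives named here were planned before the data were examined. Of 414 settings by result for counts and summaries, 392 left the result within its limits, 20 moved it and 2 took it past the threshold. For gene counts, limits were a preset ratio to the main count. No reversal could be recorded for them or for the correlation. The medians of NRF2-responsive genes could reverse and did not. A changed majority could lie within the limits, as for NRF2 with DMSO under library size alone (2307 higher, 2894 lower). Requiring at least a 2-fold change gave 518 and 321 genes higher and lower for NRF2 with DMSO, 2404 and 1191 for romidepsin in EV cells, and 2599 and 1703 in NRF2 cells. It gave 554 and 199 for NRF2 with romidepsin, 117 and 130 for the interaction, 503 and 251 for the average NRF2 effect, and 2533 and 1452 for the average romidepsin effect. An adjusted p under 0.01 gave 1503 lower for NRF2 with DMSO, and 309 and 741 for the interaction. These settings call fewer genes by construction. The genes higher with NRF2 had a median interaction of -0.036 that passed the test with fry and of -0.051 that passed with no filter. The Pearson r of the romidepsin responses was 0.656 with no filter, where genes with few counts enter; the cause of the changes in that set was not tested.

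Leaving out 1 library gave these ranges of genes higher and lower. NRF2 with DMSO ranged from 2244 to 3089 and from 1865 to 2717, and romidepsin in EV cells from 5058 to 5608 and from 4874 to 5312. Romidepsin in NRF2 cells ranged from 5240 to 5551 and from 5141 to 5575, and NRF2 with romidepsin from 2553 to 3477 and from 2508 to 3882. The interaction ranged from 465 (without replicate 2 of EV cells with romidepsin) to 921 and from 959 to 2127 (without replicate 3 of NRF2 cells with DMSO). The average NRF2 effect ranged from 3033 to 3606 and from 3239 to 4142, and the average romidepsin effect from 5698 to 5929 and from 5462 to 5730. With the replicate number as a replicate block, the interaction gave 637 and 1221 genes and NRF2 with DMSO 2507 and 2129. The numbers do not pair the libraries: residual correlations of libraries with the same number ran from -0.12 to 0.06, with 0 of 12 over 0.1.

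Of 2550 settings by list median, 2399 were the same, 48 lost the call (42 of them with an estimated correlation), 103 gained it (57 of them with fry) and 0 reversed. The same label also covers lists called in neither setting, so it does not count calls that held. With an estimated correlation, the reported list calls that held were detoxification targets in both NRF2 comparisons and glutathione targets in that with romidepsin. Of 4023 settings by named gene, 4008 were the same, 12 lost the call, all for Gsta1 in the interaction or Nfe2l2 with romidepsin in NRF2 cells, and 3 gained it. Depth sets the floor of 3 counts, 0.107 to 0.178 CPM in a single library. On simulated data the smallest changes tried were recovered in 22% of genes for the interaction, and whether depth, spread or the number of libraries limits this was not tested.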

Other observations

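The gene families described here were grouped by symbol and tested after the data were seen, in 79 families of at least 15 tested genes. None of the calls holds with an estimated correlation. Keratin genes (Krt), which build the filaments of epithelial cells, were higher in NRF2 cells in 12 of 18 cases and lower in 0, averaged over treatments (median log2 0.60; camera adjusted p = 5.0e-05; adjusted p = 0.27 with an estimated correlation). Aldehyde dehydrogenase genes (Aldh) were higher in 9 and lower in 1 of 16 (camera adjusted p = 0.017; adjusted p = 0.46 with an estimated correlation). Nuclear pore genes (Nup) were lower in 15 and higher in 1 of 20, and genes whose symbol starts with Rad, many of them of DNA repair, lower in 13 and higher in 1 of 18 (camera adjusted p = 0.00083 and 0.0082; adjusted p = 0.39 and 0.27 with an estimated correlation).

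Averaged over lines, collagen genes (Col) rose with romidepsin in 18 and fell in 3 of 24 cases, with a median log2 of 1.83 (camera adjusted p = 0.035; adjusted p = 0.47 with an estimated correlation). Genes of small GTPases of vesicle transport (Rab) rose in 41 and fell in 12 of 62 cases, and genes whose symbol starts with Atp, many of them of ion pumps and ATP synthase, rose in 41 and fell in 17 of 65 (camera adjusted p = 0.032 and 0.035; adjusted p = 0.35 and 0.56 with an estimated correlation). Zinc finger genes (Zfp) fell in 222 and rose in 57 of 345 cases (median -0.41; camera adjusted p = 0.00032; adjusted p = 0.47 with an estimated correlation). Nup genes fell in 18 and rose in 2 of 20 cases, and Rad genes fell in 14 and rose in 3 of 18 (camera adjusted p = 0.0016 and 0.036; adjusted p = 0.36 and 0.35 with an estimated correlation). RNA-binding motif genes (Rbm) fell in 23 and rose in 7 of 33 cases (camera adjusted p = 0.035; adjusted p = 0.56 with an estimated correlation). The ribosomal protein families Rpl and Rps, which overlap the list of cytosolic ribosomal proteins, fell in 43 of 47 and 31 of 43 cases and rose in 0 and 7 (camera adjusted p = 2.3e-05 and 0.042; adjusted p = 0.60 and 0.72 with an estimated correlation).

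In the interaction 7 of 18 Rad genes had a lower and 0 a higher response in NRF2 cells (median -0.28; camera adjusted p = 0.00084; adjusted p = 0.11 with an estimated correlation). Of 31 kinesin genes (Kif) 12 had a lower and 2 a higher response, and of 20 Nup genes 6 and 0 (camera adjusted p = 0.035 and 0.0073; adjusted p = 0.81 and 0.77 with an estimated correlation). Families passed in the other direction too: 9 Atp genes had a higher and 2 a lower response of 65, 6 and 1 of 18 autophagy genes (Atg) and 4 and 1 of 24 Col genes. Their camera adjusted p was 0.035, 0.049 and 0.049 (adjusted p = 0.81, 0.54 and 0.77 with an estimated correlation).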
